A study of Cricetulus griseus with 9 samples.

How the data were processed

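RNA was extracted from MI5-4 Chinese hamster ovary cells and made into mRNA libraries by the submitters, 3 for each of EV (empty vector), WTHK2 (wild-type HK2) and LAC (EV with 10 mM sodium lactate for 24 h). Per the labels, the authors used FastQC 0.11.8, cutadapt 1.18, STAR 2.7.0a, featureCounts 2.0.1 and edgeR 3.8; the genome build and annotation of the counts are not given in the sources used here. The deposited table holds normalized CPM, scaled to an effective library size set by the authors, for 6753 genes in 9 libraries, and all of its columns were used. The lowest gene mean was 20.4 CPM and the columns summed to 80.3% to 81.4% of the total that the unit implies, so lower genes were not analysed here. All values were checked to be whole multiples of a per-library step within a tolerance of 0.01, and the step gave the effective library size, 18050959 to 26238659 reads. The gene with the fewest reads in any library had 304 on this scale.

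Samples were grouped by their labels, and 3 comparisons were made: WTHK2 with EV, LAC with EV, and WTHK2 with LAC, followed by the overlap of the first 2. The tests, thresholds, gene lists, rule for naming genes and the first alternatives were fixed before the data were examined. Values were put on the scale log2(CPM + 1), genes with a mean of at least 1 CPM were kept (0 were removed), and all 9 libraries were fitted together with limma 3.58.1 in R 4.3.3, with a variance trend and no covariates. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes; the tests were two-sided. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. On simulated data with the spread of these libraries, the fit called 79.1%, 85.1% and 88.1% of genes changed 1.2-fold in the 3 comparisons. It called 100% of those changed 1.5-fold or 2-fold, and 4.12%, 6.40% and 9.86% of calls were false. In these simulations 200 of 6753 genes were changed and the noise was independent between genes. The rates therefore do not cover noise correlated between genes.

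Named genes were the listed hexokinases, the 10 largest rises and falls in each comparison with EV and the 5 largest each way between WTHK2 and LAC, among called genes with a symbol, a mean of at least 5 CPM and no overlap between the groups. They also included the 5 largest shared changes each way and, for each list, up to 4 called members with the smallest adjusted p, or up to 2 where none was called. Each of 30 gene lists was counted over all genes and adjusted over the list alone, and 25 lists with at least 3 listed members were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The lists covered hexokinases, glycolysis below hexokinase, glucose and lactate transport, the pentose phosphate pathway, hexosamine and N-glycan precursors, MondoA and ChREBP targets, the TCA cycle, oxidative phosphorylation, cholesterol and fatty acid synthesis, ATF4 targets, the unfolded protein response, hypoxia targets, extracellular matrix, stellate or myofibroblast genes, histone acylation, S phase, mitosis, interferon, NF-kB, NRF2 and p53 genes, immediate early genes, ribosome biogenesis, ribosomal proteins, lysosome, mitochondrially encoded transcripts, canonical histones, and leukocyte and epithelial markers. The shared response was described by the genes called in the same direction in both comparisons with EV and by the correlation of fold changes across genes, set against 100 simulations of unchanged groups with independent noise and, added after the data were seen, 1000 with noise drawn from the within-group residuals, which keeps the correlation between genes.

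Alternatives were other pseudocounts (0.25 and 4), a filter at 5 CPM or none, rescaling to the same median, quantile normalization, fits of the 6 libraries of a comparison, no variance trend, a robust fit, the replicate number as a block, stricter thresholds, camera with an estimated correlation, fry, and each library left out in turn. After the data were seen, voom on reads recovered from the steps, a fit without the first replicates of WTHK2 and LAC, a fit with the first component of the within-group residuals removed, and a fit without neighbouring-gene runs were added. Neighbouring genes were placed by symbol on the assembly CriGri-PICRH-1.0, which matched 6149 of 6753 genes (91.1%) and served only for gene order, with medians over windows of 15 genes set against the 95th percentile of the largest window median in 1000 shuffled orders.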

Results

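Gene expression was measured by RNA sequencing of mRNA libraries from MI5-4 cells, a Chinese hamster ovary subline that the labels describe as hexokinase null when it carries an empty vector. The 9 libraries formed 3 groups of 3: cells with the empty vector (EV), cells labelled as expressing wild-type HK2 (WTHK2), and EV cells given 10 mM sodium lactate for 24 h (LAC). The values were normalized CPM (read counts scaled to library size) for 6753 genes, and the gene with the lowest mean stood at 20.4 CPM. The listed genes summed to between 80.3% and 81.4% of the total that the unit implies in each library. All values of a library were whole multiples of a step within a tolerance of 0.01, which gives effective library sizes from 18050959 reads (WTHK2 replicate 1) to 26238659 reads (WTHK2 replicate 2). Group values below are means ± SD of the 3 libraries, and fold changes are log2 differences of CPM plus 1 from a limma fit. The labels do not state that the replicates were separate cultures, so the p-values measure only the spread between these samples. Of 30 gene lists fixed before the data were examined, 25 had at least 3 listed members and were tested with camera. The lists of canonical histone genes, leukocyte markers and epithelial markers had 0 listed members. The leukocyte, epithelial and stellate or myofibroblast lists were fixed only as a check for foreign RNA in this cell line. Every gene named below as changed had values that did not overlap between the compared groups.

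The libraries fell into their groups. On the first principal component, with 59.0% of the variance, the 3 EV libraries had scores of -12.4 to -9.24 and the 6 others 1.60 to 9.43. The second component, with 18.8%, parted the libraries labelled WTHK2 (-6.72 to -4.52) from LAC (4.18 to 5.84). Mitochondrially encoded transcripts stood above the EV mean by a median log2 value of 0.73, 0.45 and 0.40 in WTHK2 replicates 1 to 3 and by 0.80, 0.52 and 0.45 in LAC replicates 1 to 3. Genes coding for proteins above 2500 residues were lower in all 6 of these libraries, with medians of -0.22, -0.30 and -0.32 in WTHK2 and -0.33, -0.24 and -0.33 in LAC. This list was written by hand after the data were seen and was not taken from the annotation of the counts. In the limma fit 47 of its 55 genes were lower in WTHK2 and 50 of 55 in LAC, and 0 were higher in either group. Falls against EV named below were not separated from this trend.

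Hexokinase transcripts did not follow the group label. Hk2, which codes for the hexokinase that the construct is meant to supply, stood at 67.3 ± 2.11 CPM in EV, 65.3 ± 1.33 in WTHK2 and 67.8 ± 2.92 in LAC. Its log2 fold change in WTHK2 against EV was -0.044 (SE 0.054, adjusted p = 0.522), with a 95% interval of -0.156 to 0.0674, whose upper end is a fold of 1.05. In LAC against EV it was 0.010 (SE 0.054, adjusted p = 0.890). Hk1, the other listed hexokinase gene, was expressed at 324 ± 7.09 CPM in EV and fell to 285 ± 7.63 in WTHK2, a log2 fold change of -0.18 (SE 0.035, adjusted p = 3.64e-04). In LAC it stood at 302 ± 2.22 CPM, with a log2 fold change of -0.10 (SE 0.035, adjusted p = 0.0277) that did not pass with each library rescaled to the same median (-0.056, adjusted p = 0.208) or without the variance trend (adjusted p = 0.0775). It did not pass without EV replicate 1 (adjusted p = 0.125), EV replicate 2 (0.0593) or LAC replicate 3 (0.0732) either. Since Hk2 was not higher in the group labelled WTHK2, each direction given below for the libraries labelled WTHK2 rests on the label.

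**Figure D1:**
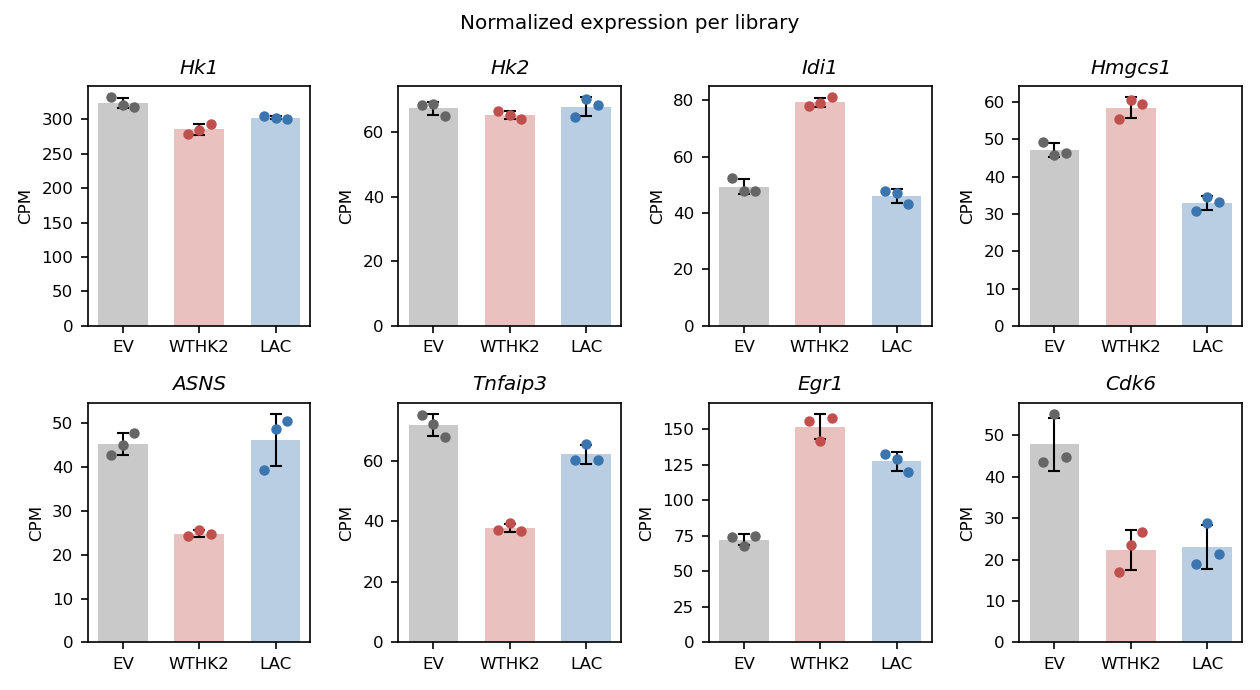
Normalized CPM (y axis) of 8 genes in the 3 groups (x axis); bars show group means, error bars the SD, and points the 3 libraries of each group. Hk2 lay near 65 to 68 CPM in all groups, Hmgcs1 was highest in the libraries labelled WTHK2 and lowest in LAC, and Cdk6 was lower in both groups than in EV.

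The first comparison, of the libraries labelled WTHK2 with EV, addressed how cells labelled as expressing HK2 differ from cells with the empty vector. Genes of cholesterol synthesis rose together, with 18 of 20 listed members higher and a median log2 fold change of 0.32 (adjusted p = 1.24e-10). ATF4 targets, which include enzymes and transporters of amino acid supply, were mostly lower, with 13 of 23 down and 1 up (adjusted p = 2.49e-05, and adjusted p = 0.173 with an estimated correlation). Egr1, an immediate early transcription factor, had the largest rise, from 72.3 ± 3.76 CPM in EV to 152 ± 8.97, a log2 fold change of 1.06 (SE 0.054, adjusted p = 2.27e-11). Cdk6, a kinase of the G1 phase of the cell cycle, had the largest fall, from 47.8 ± 6.41 to 22.4 ± 4.85 CPM, a log2 fold change of -1.08 (SE 0.14, adjusted p = 4.47e-06). Most changes were small: of 6753 genes, 3131 (46.4%) passed the threshold of an adjusted p of 0.05, 1417 higher and 1714 lower, with a median fold of 1.17 in either direction. A fold of at least 1.5 was reached by 24 higher and 62 lower genes, and a fold of at least 2 by Egr1, Ssu72 and Cdk6. The 2 groups did not overlap for 57.1% of genes, where chance gives 10%. Genes higher in WTHK2 made up 45.3% of those changed, but 57.4% with each library rescaled to the same median.

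After Egr1, the largest rise against EV in the libraries labelled WTHK2 was that of Ssu72. This gene, a phosphatase of the RNA polymerase II tail, rose from 22.0 ± 3.50 to 45.9 ± 0.811 CPM, a log2 fold change of 1.04 (SE 0.088, adjusted p = 2.80e-08), and lies in a run of 27 neighbouring genes with a median of 0.40. Cdsn, an adhesion protein of cornified epithelium, rose by 0.94 (SE 0.084, adjusted p = 4.98e-08). Nqo1, a quinone reductase and target of NRF2, rose from 23.8 ± 0.365 to 44.6 ± 1.83 CPM, by 0.88 (SE 0.074, adjusted p = 2.80e-08). The other log2 rises were 0.89 for Arhgap25, 0.88 for Sars2, 0.83 for Fcgrt, 0.80 for Acss2, 0.79 for Cebpd and 0.75 for Oxr1; Sars2 is the mitochondrial seryl-tRNA synthetase, Acss2 makes acetyl-CoA from acetate, and Cebpd is a transcription factor. Arhgap25 stood at 372 ± 78.4 CPM in the group. After Cdk6, the largest falls included its partner cyclin Ccnd2 at -0.99 (SE 0.090, adjusted p = 6.86e-08) and the transcription factor Glis3 at -0.95 (SE 0.070, adjusted p = 6.41e-09). Gpnmb, a lysosomal glycoprotein, fell from 196 ± 2.22 to 103 ± 0.180 CPM, with a log2 fold change of -0.92 (SE 0.046, adjusted p = 2.27e-11). Tnfaip3, a feedback inhibitor of NF-kB, stood at 37.8 ± 1.45 CPM against 71.7 ± 3.66 in EV, and ASNS, asparagine synthetase, at 24.9 ± 0.716 against 45.2 ± 2.50. The remaining log2 falls were -0.85 for Rc3h2, -0.84 for Prune2, -0.83 for Cpd and -0.82 for Myo5a. Genes for long proteins were lower in the same libraries (47 of 55, median -0.30), and the falls named here were not separated from that trend.

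The cholesterol synthesis list held its call with an estimated correlation (adjusted p = 0.00797 with an estimated correlation), and all 20 of its members were higher adjusted over the list alone. Idi1, an isoprenoid isomerase, rose from 49.3 ± 2.62 to 79.2 ± 1.57 CPM, by 0.68 (SE 0.060, adjusted p = 4.65e-08). Fdps, which makes farnesyl diphosphate, rose by 0.58 (SE 0.047, adjusted p = 1.90e-08), and Sqle, squalene epoxidase, by 0.42 (SE 0.034, adjusted p = 2.35e-08). Fatty acid synthesis genes went both ways, with 6 of 12 higher and 3 lower (6 and 3 adjusted over the list alone; adjusted p = 0.558). Acss2 rose, while Acaca, acetyl-CoA carboxylase, fell with a log2 fold change of -0.64 and Fasn, fatty acid synthase, with -0.24. Gpam, a glycerol-phosphate acyltransferase, fell with -0.53 and lies in a run of 55 neighbouring genes with a median of -0.18. The falls of Acaca and Fasn were not separated from the lower values of genes for long proteins (median -0.30).

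Stress response lists differed in direction in the libraries labelled WTHK2 against EV. Adjusted over the list alone, 16 ATF4 targets were lower and 1 higher. Psat1, of serine synthesis, was at -0.53 (SE 0.051, adjusted p = 1.27e-07), Slc7a5, an importer of large neutral amino acids, at -0.52 (SE 0.064, adjusted p = 3.07e-06), and the transcription factor Atf5 at -0.51 (SE 0.058, adjusted p = 1.26e-06). The unfolded protein response of the endoplasmic reticulum was higher on balance: 11 of 20 listed members were higher and 4 lower (11 and 4 adjusted over the list alone; adjusted p = 1.83e-04, and adjusted p = 0.223 with an estimated correlation). Hspa5, the main chaperone there, rose from 1408 ± 31.7 to 1906 ± 108 CPM, by 0.44 (SE 0.038, adjusted p = 4.15e-08), and the log2 rises of other chaperones and folding factors were 0.47 for Manf, 0.48 for Sdf2l1 and 0.35 for Calr. For NRF2 oxidative stress targets, 11 of 19 listed members were higher and 2 lower (11 and 3 adjusted over the list alone; adjusted p = 0.00553, and adjusted p = 0.368 with an estimated correlation). Beside Nqo1, the members with the smallest adjusted p included Prdx1, a peroxiredoxin, at 0.42, Gstm1, a glutathione transferase, at 0.33, and Txn1, thioredoxin, at 0.24. The NF-kB and inflammatory list did not pass (adjusted p = 0.0616), with 2 of 16 members higher and 7 lower, counts that were equal adjusted over the list alone. It passed with each library rescaled to the same median (adjusted p = 0.0466), without EV replicate 2 (0.0376) or WTHK2 replicate 1 (0.0293), and with the main component of the within-group spread removed (0.0251). The falls were of -0.75 for Csf1, a macrophage growth factor, -0.57 for Vcam1, an adhesion receptor, and -0.41 for Rela, an NF-kB subunit. Immediate early genes did not pass as a list (adjusted p = 0.284), with 4 and 2 of 15 higher and lower, the same adjusted over the list alone. Beside Egr1, Ier3 rose by 0.71 (SE 0.058, adjusted p = 2.34e-08), and Dusp4, a phosphatase of MAP kinases, was at -0.42. Of 13 p53 targets 1 was higher and 1 lower (1 and 0 adjusted over the list alone; adjusted p = 0.999).

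Transcripts of mitochondrial respiration and of ribosomes were higher in the libraries labelled WTHK2 than in EV. Of nuclear-encoded oxidative phosphorylation genes, 45 of 57 listed members were higher and 0 lower, with a median of 0.20 (adjusted p = 2.89e-13, and adjusted p = 0.223 with an estimated correlation). Ndufb7, of complex I, rose from 81.7 ± 2.87 to 108 ± 2.24 CPM, by 0.40 (SE 0.047, adjusted p = 1.69e-06), and Uqcrfs1, of complex III, by 0.33 (SE 0.039, adjusted p = 1.56e-06). Cytosolic ribosomal protein genes were higher in 32 of 34 cases and lower in 0, with a median of 0.19 (adjusted p = 2.89e-13, and adjusted p = 0.223 with an estimated correlation). Rps9 rose by 0.26, Rpl31 by 0.24 and Rpl22l1 by 0.53. All 4 mitochondrially encoded transcripts were higher, with a median of 0.52 (adjusted p = 0.00252, and adjusted p = 0.344 with an estimated correlation). CYTB, of complex III, rose from 1437 ± 44.4 to 2124 ± 293 CPM. Counts of these 3 lists were the same adjusted over the list alone. Beside them stand the lower genes for long proteins (median -0.30) and the first replicate, in which mitochondrially encoded transcripts were highest.

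Lists of glucose use changed in part in the libraries labelled WTHK2. Of 8 glycolysis genes below hexokinase, Aldoa, an aldolase, rose by 0.18 (SE 0.039, adjusted p = 9.73e-04) and Pfkfb3, which makes the activator of phosphofructokinase, fell from 36.5 ± 1.12 to 23.6 ± 2.64 CPM, -0.61 (SE 0.084, adjusted p = 9.48e-06). That list did not pass (adjusted p = 0.852), and its median of 0.020 and mean of -0.034 differ in sign. Transporters and genes of lactate oxidation were higher in 4 of 7 cases and lower in 0 (adjusted p = 0.284), among them Bsg, a partner of lactate transporters, at 0.16 (SE 0.039, adjusted p = 0.00264). Pentose phosphate genes counted 3 higher and 2 lower of 8 (adjusted p = 0.558), with transketolase (Tkt) at 0.18 (SE 0.031, adjusted p = 1.01e-04). Hexosamine and N-glycan precursor genes were higher in 9 of 21 cases and lower in 3 (adjusted p = 0.0349, and adjusted p = 0.212 with an estimated correlation); DPAGT1, which starts the N-glycan precursor, was at 0.14, and Ogt, which attaches O-GlcNAc, at -0.26. The call was lost without EV replicate 1 (adjusted p = 0.0578) or WTHK2 replicate 3 (adjusted p = 0.0634). Tmem97, the only listed member of the MondoA and ChREBP list, rose by 0.38 (SE 0.072, adjusted p = 3.04e-04). With 1 member that list was not tested, and this gene cannot stand for it. Of 22 TCA cycle genes 8 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.258), and Idh1, the cytosolic isocitrate dehydrogenase, rose by 0.39 (SE 0.073, adjusted p = 2.36e-04). With the main component of the within-group spread removed the TCA cycle list passed (adjusted p = 0.00302), with a mean of 0.097 against 0.044. Counts of the glycolysis, transport, pentose and hexosamine lists were the same adjusted over the list alone.

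In the libraries labelled WTHK2 the stellate or myofibroblast list passed, and the lists after it in this paragraph did not. Since the samples are a single cell line, its call is not read as a change of cell type. In the stellate or myofibroblast list 7 of 12 listed members were higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.00976, and adjusted p = 0.173 with an estimated correlation). S100a6, a calcium-binding protein, rose by 0.47 (SE 0.042, adjusted p = 4.64e-08), and Vim, vimentin, from 2632 ± 29.9 to 3269 ± 88.7 CPM. Extracellular matrix genes split evenly, 7 higher and 7 lower of 18 (7 and 8 adjusted over the list alone; adjusted p = 0.802), with a median of -0.019 and a mean of 0.016. Col3a1, a fibrillar collagen, rose by 0.56 (SE 0.043, adjusted p = 1.12e-08), and Col12a1 was lower at -0.54. Of hypoxia targets 4 were higher and 3 lower of 12 (4 and 4 adjusted over the list alone; adjusted p = 0.852); the median was 0.027 and the mean -0.012, and Hif1a, the oxygen-regulated subunit itself, was at -0.26. The S phase list counted 2 higher and 15 lower of 40 (adjusted p = 0.0865), with Rfc1, of the clamp loader, at -0.40. The mitosis list counted 6 and 6 of 37 (adjusted p = 0.694), with Top2a, topoisomerase II, at -0.24 and Aurka, a spindle kinase, at 0.27. Histone acylation genes were higher in 3 of 25 cases and lower in 10 (adjusted p = 0.330), and the acetyltransferases Ep300 and Kat6a were at -0.25 and -0.52. Of 31 lysosome and autophagy genes 5 were higher and 10 lower (adjusted p = 0.312), with Psap, the saposin precursor, at -0.39. Ribosome biogenesis counted 5 and 9 of 32 (adjusted p = 0.558) and interferon genes 2 and 3 of 10 (adjusted p = 0.833). Tap1, a peptide transporter of antigen presentation, rose by 0.32 and Utp20, of ribosome assembly, was at -0.32. Counts of the last 6 lists were the same adjusted over the list alone. The medians of the matrix, histone acylation, interferon, p53 and ribosome biogenesis lists changed sign under at least 1 of the 2 other scalings. Falls in this paragraph, such as those of Col12a1, Ep300, Kat6a and Utp20, were not separated from the lower genes for long proteins (median -0.30).

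The second comparison, of LAC with EV, addressed what sodium lactate does to empty-vector cells. Immediate early genes rose on balance: 10 of 15 listed members were higher and 3 lower, with a median log2 fold change of 0.23 (adjusted p = 0.00131, and adjusted p = 0.171 with an estimated correlation). Egr1 rose from 72.3 ± 3.76 to 127 ± 6.43 CPM, a log2 fold change of 0.81 (SE 0.054, adjusted p = 8.82e-09), and Dusp1, a phosphatase of MAP kinases, from 72.4 ± 3.40 to 106 ± 3.73 CPM. The chemokine Cxcl1 rose by 0.63 (SE 0.074, adjusted p = 2.45e-06) and the chemokine Ccl2 by 0.56 (SE 0.059, adjusted p = 9.18e-07). Cdk6 fell from 47.8 ± 6.41 to 23.0 ± 5.24 CPM, a log2 fold change of -1.04 (SE 0.14, adjusted p = 7.18e-06). In all, 3341 of 6753 genes (49.5%) passed the threshold, 1512 higher and 1829 lower, with a median fold of 1.18 in either direction. A fold of at least 1.5 was reached by 9 higher and 77 lower genes, and a fold of at least 2 by 0 higher genes and by Cdk6, Tet3 and Cpd, which were lower. The groups did not overlap for 57.8% of genes, against 10% by chance. Higher genes made up 45.3% of those changed and 58.6% with each library rescaled to the same median.

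The other large rises with lactate were partly of mitochondrial transcripts. ND4, of complex I, rose by 0.69 (SE 0.10, adjusted p = 1.99e-05) and CYTB from 1437 ± 44.4 to 2244 ± 308 CPM, by 0.63 (SE 0.075, adjusted p = 2.61e-06). Further log2 rises were 0.69 for Arhgap25, 0.67 for Dqx1, 0.65 for Lmtk3, 0.64 for Prr22 and 0.63 for Lcat; Lcat codes for the plasma enzyme that esterifies cholesterol. Tet3, a dioxygenase of 5-methylcytosine, fell from 55.8 ± 7.45 to 27.2 ± 4.86 CPM, a log2 fold change of -1.01 (SE 0.11, adjusted p = 1.45e-06). Abca1, a cholesterol exporter, was at -0.92 (SE 0.10, adjusted p = 8.01e-07), and Deptor, an inhibitor of mTOR, at -0.89 (SE 0.12, adjusted p = 6.24e-06). Cpd, a carboxypeptidase of the secretory pathway, was at -1.01 (SE 0.11, adjusted p = 1.52e-06), and the remaining log2 falls were -0.92 for Heg1, -0.91 for Klhl42, -0.90 for Prune2, -0.89 for Rc3h2 and -0.86 for Akap13. Genes for long proteins were lower in the same libraries (50 of 55, median -0.31), and the falls named here were not separated from that trend.

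Cholesterol synthesis did not rise with lactate: 2 of 20 listed members were higher and 9 lower (4 and 9 adjusted over the list alone), with a median of -0.10, and the list did not pass (adjusted p = 0.236). Hmgcs1, which makes the first committed precursor of mevalonate, fell from 47.1 ± 1.85 to 32.9 ± 1.90 CPM, a log2 fold change of -0.51 (SE 0.065, adjusted p = 5.12e-06). Srebf2, the transcription factor of the pathway, was at -0.35 (SE 0.047, adjusted p = 9.85e-06) and Lss, lanosterol synthase, at -0.43 (SE 0.065, adjusted p = 2.49e-05). Fatty acid synthesis counted 1 higher and 6 lower of 12, the same adjusted over the list alone (adjusted p = 0.0920), with Acaca at -0.79 and the desaturase Scd2 at -0.33. The fall of Acaca was not separated from the lower values of genes for long proteins (median -0.31). Glycolysis below hexokinase passed, with 6 of 8 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.0344, and adjusted p = 0.296 with an estimated correlation). Pgam1, a phosphoglycerate mutase, rose by 0.27 (SE 0.034, adjusted p = 4.99e-06), Aldoa by 0.28 (SE 0.039, adjusted p = 1.09e-05) and GPI, glucose-phosphate isomerase, by 0.21, while Pfkfb3 was lower at -0.62. That call did not hold with each library rescaled to the same median (adjusted p = 0.0513) or with quantile normalization (adjusted p = 0.0880). The mean log2 fold change of the list was 0.13 and 0.085 with these scalings, against 0.089 in the main fit. The lactate and glucose transport list did not pass (adjusted p = 0.520), with 3 higher and 0 lower of 7, the same adjusted over the list alone; its median was -0.019 and its mean 0.055. Slc2a1, a glucose transporter, was higher by 0.21 (SE 0.057, adjusted p = 0.00449), but stood at -0.0062 (adjusted p = 0.906) with the main component of the within-group spread removed.

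Respiration and ribosome transcripts were higher with lactate as well. For oxidative phosphorylation 51 of 57 listed members were higher and 0 lower (52 and 0 adjusted over the list alone), with a median of 0.25 (adjusted p = 1.88e-18, and adjusted p = 0.292 with an estimated correlation). Atp5j, of the ATP synthase, rose from 189.6 ± 0.753 to 243 ± 12.0 CPM, by 0.36 (SE 0.040, adjusted p = 1.52e-06), and Cox6c, of complex IV, by 0.37. Cytosolic ribosomal protein genes were higher in 33 of 34 cases and lower in 0, with a median of 0.26 (adjusted p = 7.86e-20, and adjusted p = 0.292 with an estimated correlation); Rps18 rose by 0.37 and Rpl39 by 0.37. All 4 mitochondrially encoded transcripts were higher, with a median of 0.59 (adjusted p = 0.00142, and adjusted p = 0.322 with an estimated correlation). Counts of the last 2 lists were the same adjusted over the list alone. Beside these lists, genes for long proteins were lower (median -0.31) and the first LAC replicate had the highest mitochondrially encoded transcripts.

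The other lists did not pass in LAC against EV, though members of each changed. ATF4 targets counted 7 and 4 of 23 higher and lower (adjusted p = 0.520), with Ppp1r15a, a phosphatase subunit of the stress response, at 0.42 (SE 0.062, adjusted p = 2.14e-05) and Slc7a5 at -0.54. The unfolded protein response counted 9 and 5 of 20 (adjusted p = 0.371), with Manf at 0.30 and Sel1l, of the degradation complex, at -0.65. NF-kB genes counted 5 and 4 of 16 (adjusted p = 0.520); Ccl7 rose with the other chemokines by 0.48, and Csf1 was at -0.32. NRF2 targets counted 6 and 6 of 19 (adjusted p = 0.562), p53 targets 4 and 0 of 13 (adjusted p = 0.520) and hypoxia targets 5 and 2 of 12 (adjusted p = 0.520), with Vegfa, a vascular growth factor, at 0.28 (SE 0.057, adjusted p = 4.00e-04). The stellate or myofibroblast list counted 6 and 2 of 12 (adjusted p = 0.0748; 0.0497 without EV replicate 3, 0.0457 with the replicate number as a block, and 0.0444 without the first replicates of WTHK2 and LAC), with Ccn2, a matricellular protein, at 0.45. Matrix genes counted 4 and 7 of 18 (adjusted p = 0.520), with Fn1, fibronectin, at -0.33. Histone acylation genes counted 3 and 8 of 25 (adjusted p = 0.643), with Ep300 at -0.31 (SE 0.047, adjusted p = 2.81e-05) and Kat6a at -0.56. S phase counted 6 and 7 of 40 (adjusted p = 0.862), mitosis 7 and 8 of 37 (adjusted p = 0.820) and ribosome biogenesis 10 and 5 of 32 (adjusted p = 0.317), with Anln, anillin of the cleavage furrow, at -0.57 and Nop56, of box C/D particles, at 0.30. Lysosome genes counted 6 and 9 of 31 (adjusted p = 0.973), with the protease Ctsl at 0.27, and interferon genes 3 and 3 of 10 (adjusted p = 0.552), with Bst2, tetherin, at 0.32. TCA cycle genes counted 6 and 3 of 22 (adjusted p = 0.552), pentose phosphate genes 1 and 2 of 8 (adjusted p = 0.982) and hexosamine genes 6 and 1 of 21 (adjusted p = 0.520), with Suclg1, of succinyl-CoA ligase, at 0.17 and Alg9, a mannosyltransferase, at -0.33. Tmem97 stood at 0.19 (SE 0.072, adjusted p = 0.0311), and did not pass without EV replicate 1 (adjusted p = 0.0956), EV replicate 2 (0.113), LAC replicate 1 (0.0759) or LAC replicate 3 (0.0911). Falls in this paragraph, such as those of Fn1, Ep300 and Kat6a, were not separated from the lower genes for long proteins (median -0.31).

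Adjusted over the list alone, the counts in LAC against EV were 10 and 5 for the unfolded protein response, 7 and 6 for NRF2 targets, 2 and 0 for p53 targets, 5 and 7 for S phase genes and 5 and 1 for hexosamine genes, and those of the other lists of the last paragraph were the same. With the main component of the within-group spread removed, the TCA cycle (adjusted p = 0.0156, with a mean of 0.070 against 0.0052), matrix (0.0229) and cholesterol lists (0.0392) passed. Median and mean differed in sign for NRF2 targets (-0.012 and 0.012) and S phase genes (0.016 and -0.0083), and for lysosome genes both were negative (-0.048 and -0.0072) while camera pointed up. The medians of the NRF2, matrix, transport, histone acylation, mitosis and pentose phosphate lists changed sign under at least 1 of the 2 other scalings.

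The third comparison set the libraries labelled WTHK2 directly against LAC and addressed where the 2 groups differ. Cholesterol synthesis was higher in WTHK2: 18 of 20 listed members were higher and 0 lower (19 and 0 adjusted over the list alone), with a median log2 fold change of 0.43 (adjusted p = 9.11e-24, and adjusted p = 7.01e-04 with an estimated correlation). Hmgcs1 stood at 58.5 ± 2.73 CPM against 32.9 ± 1.90, a log2 fold change of 0.81 (SE 0.065, adjusted p = 1.93e-08). ATF4 targets were lower in WTHK2 in 17 of 23 cases and higher in 0, the same adjusted over the list alone (adjusted p = 2.03e-14, and adjusted p = 0.0132 with an estimated correlation). NF-kB and inflammatory genes were lower in 10 of 16 cases and higher in 0, the same adjusted over the list alone (adjusted p = 1.94e-08, and adjusted p = 0.0129 with an estimated correlation). In all 1089 of 6753 genes (16.1%) passed, 565 higher and 524 lower in WTHK2, with a median fold of 1.16 in either direction and 29.0% of genes without overlap, against 10% by chance. A fold of at least 1.5 was reached by 17 higher and 7 lower genes, and a fold of at least 2 by 0; 1982 genes had an unadjusted p under 0.05. Without WTHK2 replicate 3 the number changed was 662, and without LAC replicate 3 it was 701. It was 1279 without WTHK2 replicate 1, and 1836 with the main component of the within-group spread removed.

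Among the largest differences, Ssu72 was higher in WTHK2 by 0.93 (SE 0.088, adjusted p = 2.32e-07), again within its run of 27 neighbouring genes (median 0.24), and Cdsn by 0.83 (SE 0.084, adjusted p = 6.56e-07). Thbs1, the matrix protein thrombospondin-1, stood at 222 ± 9.63 CPM in WTHK2 and 124 ± 11.7 in LAC, 0.84 (SE 0.053, adjusted p = 1.30e-09). Noxa1, an activator of NADPH oxidase, stood at 26.5 ± 2.73 CPM against 51.8 ± 2.81, a log2 difference of -0.94 (SE 0.075, adjusted p = 1.88e-08). ASNS stood at 24.9 ± 0.716 CPM against 46.2 ± 5.97, -0.86 (SE 0.081, adjusted p = 2.32e-07), and the transcription factor Atf4 at -0.33, Atf5 at -0.51 and Cars, cysteinyl-tRNA synthetase, at -0.33. Tnfaip3 was at -0.70 (SE 0.060, adjusted p = 6.34e-08), and the log2 differences of Csf1, Vcam1 and Nfkb2 were -0.44, -0.48 and -0.36; Nfkb2 lies in a run of 55 neighbouring genes with a median of -0.17. Gpnmb stood at -0.71 (SE 0.046, adjusted p = 1.30e-09) and Col6a2, a collagen of the pericellular matrix, at -0.84 (SE 0.091, adjusted p = 1.40e-06). Within the cholesterol list, Sqle, Msmo1 and Idi1 differed by 0.53, 0.68 and 0.77.

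Of 25 lists, 14 passed between the libraries labelled WTHK2 and LAC, and the 11 beside those above lost their call with an estimated correlation. The unfolded protein response was higher in WTHK2 in 14 of 20 cases and lower in 2 (15 and 2 adjusted over the list alone; adjusted p = 1.13e-07, and adjusted p = 0.0753 with an estimated correlation), with Hspa5 at 0.37 (SE 0.038, adjusted p = 6.60e-07). NRF2 targets counted 8 and 1 of 19 (adjusted p = 6.62e-04, and adjusted p = 0.264 with an estimated correlation), with Prdx1 at 0.33 and Gsr, glutathione reductase, at 0.39. Fatty acid synthesis counted 5 and 1 of 12 (6 and 1 adjusted over the list alone; adjusted p = 6.62e-04, and adjusted p = 0.0753 with an estimated correlation), with Scd1 at 0.40 and Scd2 at 0.46. Glycolysis genes were lower in WTHK2 in 3 of 8 cases and higher in 0 (0 and 5 adjusted over the list alone; adjusted p = 6.62e-04, and adjusted p = 0.0753 with an estimated correlation), with Pgam1 at -0.31 and Pfkl, a phosphofructokinase, at -0.21. Immediate early genes counted 2 and 6 of 15 (3 and 9 adjusted over the list alone; adjusted p = 0.00334, and adjusted p = 0.0753 with an estimated correlation): Egr1 was higher in WTHK2 by 0.25, and Dusp1, Fosl1 and Myc stood at -0.53, -0.25 and -0.23. S phase genes counted 1 and 7 of 40 (1 and 8 adjusted over the list alone; adjusted p = 6.62e-04, and adjusted p = 0.0753 with an estimated correlation), with Mcm2, of the replicative helicase, at -0.15. Ribosome biogenesis counted 0 and 8 of 32 (0 and 9 adjusted over the list alone; adjusted p = 6.62e-04, and adjusted p = 0.131 with an estimated correlation), with Rrp12 at -0.21, and cytosolic ribosomal proteins 1 and 11 of 34 (1 and 15 adjusted over the list alone; adjusted p = 2.33e-06, and adjusted p = 0.356 with an estimated correlation). Lysosome genes counted 1 and 6 of 31 (adjusted p = 0.0184, and adjusted p = 0.265 with an estimated correlation), with Gaa, acid glucosidase, at -0.27. Oxidative phosphorylation counted 1 and 8 of 57 (1 and 10 adjusted over the list alone; adjusted p = 0.00329, and adjusted p = 0.538 with an estimated correlation), a call lost without LAC replicate 1 (adjusted p = 0.0879), and Uqcrfs1 ran the other way at 0.15. Matrix genes counted 6 and 3 of 18 (8 and 4 adjusted over the list alone; adjusted p = 0.0308, and adjusted p = 0.465 with an estimated correlation), with Col3a1 at 0.58. That call was lost without WTHK2 replicate 1 (adjusted p = 0.102), WTHK2 replicate 3 (0.0651) or LAC replicate 3 (0.159). Counts of the NRF2 and lysosome lists were the same adjusted over the list alone.

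The lists that did not pass between the libraries labelled WTHK2 and LAC were transport (1 and 0 of 7 higher and lower; adjusted p = 0.750), whose median of -0.0077 and mean of 0.039 differ in sign, pentose phosphate (2 and 0 of 8; adjusted p = 0.356), hexosamine (3 and 1 of 21; adjusted p = 0.0764) and TCA cycle genes (3 and 1 of 22; adjusted p = 0.371). Hypoxia targets (1 and 2 of 12; adjusted p = 0.445), stellate or myofibroblast genes (4 and 2 of 12; adjusted p = 0.535), histone acylation genes (1 and 3 of 25; adjusted p = 0.371) and mitosis genes (7 and 1 of 37; adjusted p = 0.181) did not pass either. Calls were gained by the hexosamine list without LAC replicate 1 (adjusted p = 0.0492) or without the runs of neighbouring genes (0.0241), by mitosis genes without WTHK2 replicate 3 (0.0446) and by mitochondrially encoded transcripts without WTHK2 replicate 1 (0.0365). Interferon genes (1 and 2 of 10; adjusted p = 0.445), p53 targets (0 and 3 of 13; adjusted p = 0.193) and mitochondrially encoded transcripts (0 and 0 of 4; adjusted p = 0.371) completed these lists. Adjusted over the list alone the counts were 3 and 2 for hexosamine, 4 and 4 for stellate or myofibroblast, 1 and 4 for histone acylation, 9 and 2 for mitosis and 1 and 3 for interferon genes, and the same for the others. Tgfbr2, a receptor for TGF-beta, was higher in WTHK2 by 0.45 (SE 0.047, adjusted p = 9.67e-07), and Vegfa was at -0.45, Ccl2 at -0.42 and AARS, an alanyl-tRNA synthetase, at -0.19.

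**Figure D2:**
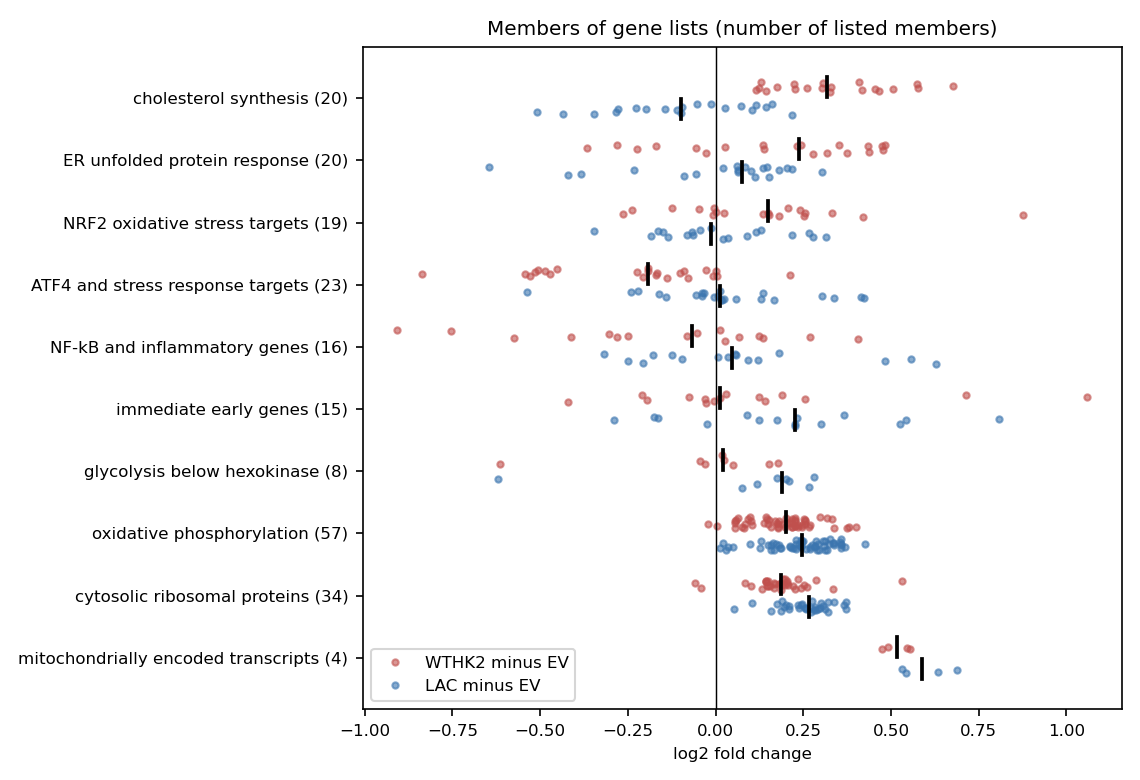
Log2 fold changes (x axis) of the listed members of 10 gene lists (y axis, with the number of members), red for WTHK2 minus EV and blue for LAC minus EV; points are genes and black ticks list medians. Cholesterol synthesis has a median of 0.32 in the libraries labelled WTHK2 and -0.097 in LAC, while the medians of oxidative phosphorylation and ribosomal protein genes lie above 0 in both.

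The last comparison addressed whether the same genes changed against EV in LAC and in the libraries labelled WTHK2. In the libraries labelled WTHK2 and in LAC, 924 genes were higher and 1313 lower than EV in both, where independent sets of this size would share 317 and 464. The excess does not by itself show a shared response, since the 2 comparisons are not independent. The shared genes made up 71.5% of the genes changed in WTHK2 and 67.0% of those changed in LAC. Egr1, Arhgap25, Lmtk3, CYTB and ND4 had the largest shared rises, and Cdk6, Rc3h2, Prune2, Cpd and Arhgef12 the largest shared falls. Arhgef12, a guanine nucleotide exchange factor, fell from 161 ± 12.7 CPM to 94.0 ± 9.13 in WTHK2 and 92.3 ± 15.1 in LAC, log2 fold changes of -0.77 (SE 0.085, adjusted p = 6.80e-07) and -0.81 (SE 0.085, adjusted p = 8.96e-07). Lmtk3, a membrane kinase, rose by 0.62 (SE 0.093, adjusted p = 2.53e-05) in WTHK2 and by 0.65 in LAC. Across 6753 genes, which are not independent replicates, the fold changes of the 2 comparisons had a Pearson r of 0.794, a Spearman correlation of 0.799 and a covariance of 0.0346. Both comparisons use the same EV libraries, and 100 simulations of unchanged groups with independent noise gave a mean r of 0.501 and a mean covariance of 0.00199 (highest 0.00217). With noise correlated between genes as within the groups, 17.1% of 1000 simulations reached this r, while the highest covariance was 0.0160; the r alone therefore does not show a shared response. With 3 EV libraries the controls could not be split into separate sets of at least 2. Changed genes went in opposite directions in 43 cases, among them Hmgcs1 and Thbs1, which were higher in WTHK2 and lower in LAC, and Noxa1 and Atf4, which were the reverse.

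**Figure D3:**
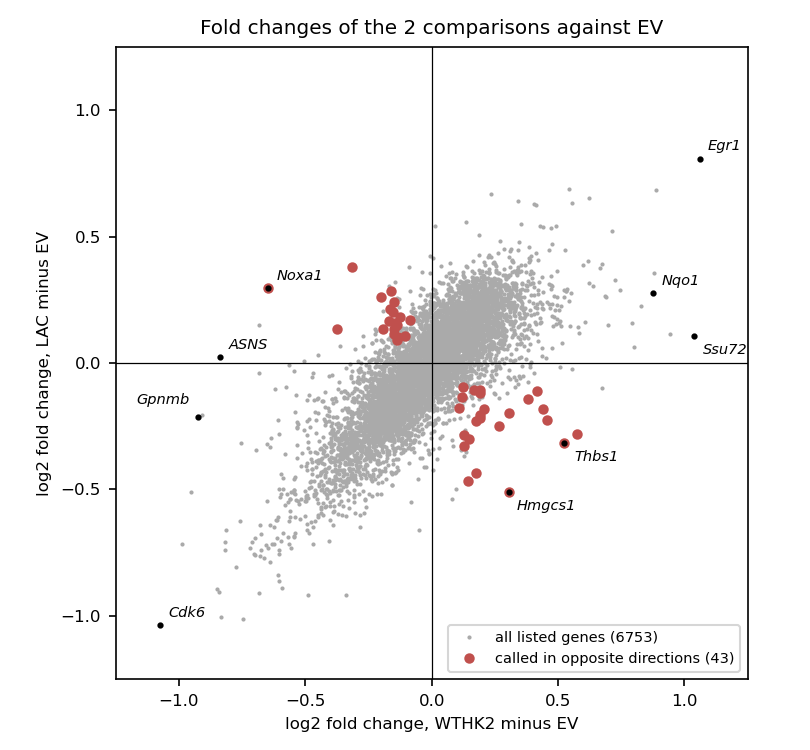
Log2 fold changes of WTHK2 minus EV (x axis) and of LAC minus EV (y axis) for 6753 genes; each point is a gene, and red points are the 43 genes called in opposite directions. Most points lie along the rising diagonal (r 0.794), with Egr1 at the upper and Cdk6 at the lower end.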

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

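The bounds on the covariance, the test of genes for long proteins, the tests of neighbouring genes against shuffled orders and in the lactate libraries and both tests of Hk2 were chosen only after the result was seen, and the removal of the within-group component was added after the data were seen.

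Genes called in opposite directions in the 2 comparisons with EV numbered 43, and they are listed because the 2 groups lay on opposite sides of EV. The difference between the libraries labelled WTHK2 and LAC passed for each of them, which adds no support, since in a joint fit it is the sum of both shifts. Of these, 24 were higher than EV in WTHK2 and lower in LAC. They include the cholesterol genes Hmgcs1 (log2 fold changes of 0.30 and -0.51), Msmo1 (0.45 and -0.23), Sqle (0.42 and -0.11) and Lss (0.17 and -0.43), the desaturases Scd1 and Scd2, and Thbs1 (0.53 and -0.32). Another 19 were lower in WTHK2 and higher in LAC, among them Noxa1 (-0.65 and 0.30), Ankrd1 (-0.32 and 0.38), Vegfa (-0.16 and 0.28) and Atf4 (-0.17 and 0.17). The genes beyond those of the naming rule were chosen after their values were seen.

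The fold changes of both groups against EV ran together (r 0.794). Replicate noise of the shared EV libraries as the whole cause is argued against by the covariance of 0.0346, above the highest of 1000 simulations with correlated noise (0.0160). An offset common to all 3 EV libraries was not simulated, would enter both fold changes alike, and stays open. The main within-group component as the whole cause is argued against by the covariance of 0.0194 without it, above the highest such value (0.00769). Its removal still took away part of the covariance. The bound on r set beforehand decides nothing, since 37.1% of those simulations reached the r of 0.694. A trend with transcript length between EV and the other libraries stays open: genes for long proteins had a median of -0.30 in WTHK2 and -0.31 in LAC, and 0% of 10000 random lists matched on expression lay lower in either. The list was written by hand, and protein length stands in it for transcript length, which was not available. Such a trend may come from RNA quality or library preparation, since all 3 EV libraries lie on its other side and the labels name no batch, or from the cells themselves. A common effect of lactate, whether added or made through HK2, is the biological explanation that the design offers and stays open as a hypothesis.

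Runs of neighbouring genes shifted together: of 5992 windows of 15 genes, 27 passed the 95th percentile of the largest median in 1000 shuffled orders in WTHK2 against EV (10 higher, 17 lower), 0 in LAC against EV and 140 between the libraries labelled WTHK2 and LAC. The 5 runs were taken from the last of these comparisons only; 4 were shifted in WTHK2 and that from Abcb10 to Itgb1 was not. The lowest window in WTHK2 against EV (-0.307) was centred on Atad1, which is in none of the 5 runs. Chance placement is argued against by the largest window median of 0.308 between WTHK2 and LAC, above the largest of 1000 shuffled orders (0.203). A trend also present in the lactate libraries was set against a bound of 0.5 of the WTHK2 shift. In 3 runs the LAC medians (-0.014, -0.010 and 0.013) were at most 0.0817 of those in WTHK2 (-0.18, -0.15 and 0.17), below that bound. From Noc2l to Dnajc11 the share was 0.290, and 13 of 27 genes were higher in LAC (medians of 0.17, 0.079 and 0.14 in the 3 libraries). The runs were chosen by the difference between WTHK2 and LAC, which favours a small share in LAC. These shares therefore cannot decide whether such a trend is present, and it stays open. A segment copy number difference of the WTHK2 line stays open as a candidate explanation, although a change in that line alone would not give the shift of LAC. Genes inside the 5 runs spread around their run's median 1.10 times as widely as genes outside, below the bound of 1.5. This ratio decides little, since each run's own median was taken off first and the 5 runs include the 1 not shifted in WTHK2. Regional regulation might leave the same ratio, and nothing in the table tests DNA.

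Hk2 was not higher in the libraries labelled WTHK2. An exchange of EV and WTHK2 libraries, with the introduced transcript counted under Hk2, needs Hk2 to be higher in the libraries labelled EV by more than 2 SE, and the log2 difference of WTHK2 from EV was -0.044 (SE 0.054). An introduced HK2 transcript that was not counted under Hk2, for example because its sequence differs from the hamster gene, could leave these values as they are, and the log2 difference of WTHK2 from LAC was -0.054 (SE 0.054). That cannot be told apart from a construct expressed at a low level, because the table holds no reads of the construct as such. No biological explanation was tested.

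Splits of the 6 libraries of a comparison, with the real one, number 10 and are too few for a share under 0.05. As many genes as the real split were called by 1 of 10 in WTHK2 against EV (3131, highest other 0), 1 of 10 in LAC against EV (3341, highest other 0) and 1 of 10 in WTHK2 against LAC (1089, highest other 28). As many lists were called by 1 of 10 (9, highest other 7), 2 of 10 (5, highest other 6) and 1 of 10 (14, highest other 10). For the genes changed alike in both groups, 1 of 100 splits of the 9 libraries, the real one, gave as many (2237). The highest other count was 505. This argues against a random sorting of the libraries into groups, if they are exchangeable, which the labels do not state. It cannot tell a shared response from an offset common to the EV libraries, which would enter both comparisons alike.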

How the results depend on the processing

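Voom on recovered reads, the fit without the first replicates of WTHK2 and LAC, the fit without the main within-group component and the fit without neighbouring-gene runs were chosen only after the data were seen. The planned count models on recovered reads (edgeR and DESeq2) were not run, because the recovery could not be checked on low values, which are absent. The values present were all whole multiples of a per-library step, and voom was run on the same recovered reads. The lack of low values therefore did not prevent these models from being run, and what they would have called was not tested. Filters at 5 CPM and none removed 0 genes more or less and test nothing. The lowest gene had 304 reads, and replicates differed by 3.32 to 8.91 times the counting variance; depth and the number of libraries were not compared as limits.

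With other pseudocounts, both scalings, the 6 libraries of a comparison, no variance trend, a robust fit or voom (3191, 3353 and 1097 genes), the counts of changed genes stayed within 1.5 times of 3131, 3341 and 1089. Calls turned direction for 1 gene in WTHK2 against EV with quantile normalization, and for 4 and 13 genes in the comparisons with EV without the within-group component. Without that component, 2362 of the 3131 calls in WTHK2 against EV and 2274 of the 3341 in LAC against EV were kept in the same direction. The fit without it called 3333 and 3291 genes in these comparisons. At an adjusted p under 0.01, 941 genes were higher and 1207 lower in WTHK2 than in EV, 998 higher and 1371 lower in LAC, 541 differed between WTHK2 and LAC (281 higher, 260 lower) and 1399 were shared. At a fold of at least 2 the counts were 3 (2 higher, 1 lower), 3 (0 and 3) and 0 (0 and 0), with 1 gene, Cdk6, shared. The stricter thresholds lower the counts by construction.

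With each library left out in turn, WTHK2 against LAC ranged from 662 genes without WTHK2 replicate 3 (333 higher, 329 lower) and 701 without LAC replicate 3 to 1279 without WTHK2 replicate 1 (650 and 629). WTHK2 against EV ranged from 2445 to 3291, LAC against EV from 2650 to 3511, shared genes from 1619 to 2383, r from 0.745 to 0.813, and lists from 8 to 10, 5 to 6 and 13 to 14. Without the first replicates of WTHK2 and LAC, 2941, 3054 and 1100 genes were changed and r was 0.734. Without the runs of neighbouring genes, 2948, 3206 and 865 genes were changed. Without the within-group component 1836 genes differed between WTHK2 and LAC (951 higher, 885 lower), r was 0.694, 8 lists passed in LAC against EV, and Slc2a1 went from 0.15 to -0.034 in WTHK2 and from 0.21 to -0.0062 in LAC. The cause was not tested.

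Lists past the threshold numbered 1, 0 and 3 with an estimated correlation and 16 and 11 in the comparisons with EV by fry, which does not compare a list with other genes. LAC against EV had 3 lists with quantile normalization, which sets COX1, the highest gene of every library and 1 of 4 mitochondrially encoded transcripts, equal by construction; that list kept medians of 0.49 (WTHK2) and 0.55 (LAC), so its lost calls say nothing, and for glycolysis the cause was not tested. Over all alternatives, list results kept their side of the threshold in 1657 cases, were no longer past in 36, newly past in 32 and reversed in 0. Named genes did so in 7253, 174, 4 and 2. Direction was compared only where a result passed in the main fit or the alternative. Changes of sign among results past in neither are therefore not counted as reversed. The filters at 5 CPM and none repeat the main fit, and each adds 75 list and 324 named-gene cases to the results that kept their side. With the replicate number as a block (replicate block), 3433, 3609 and 1414 genes were changed. The block was not used elsewhere, since the labels do not state that equal numbers share a day or batch. Of 9 pairs with an equal number 4 correlated above 0.1, and 7 of 9 libraries matched best a library with their own number. A pairing by replicate number therefore stays open.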

Other observations

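The gene families below were defined by their symbols only after the data were seen, as 10 families tested together. Mitochondrial ribosomal protein genes were higher than EV in both groups, 42 of 69 in the libraries labelled WTHK2 (median log2 fold change 0.19, adjusted p = 9.09e-11, and adjusted p = 0.138 with an estimated correlation) and 51 of 69 in LAC (median 0.22, adjusted p = 2.11e-12, and adjusted p = 0.140 with an estimated correlation), with 0 lower in either. Proteasome subunits were higher in 30 of 40 cases and lower in 1 in WTHK2, and higher in 27 and lower in 4 in LAC (adjusted p = 9.11e-10 and 2.91e-06, and adjusted p = 0.138 and 0.140 with an estimated correlation). Histone lysine demethylases and TET dioxygenases, which remove methyl groups from histones and oxidize those of DNA, were lower in 9 of 15 cases in both groups and higher in 0 (adjusted p = 0.00215 and 0.00400, and adjusted p = 0.138 and 0.140 with an estimated correlation). Tet3 fell with a log2 fold change of -0.75 (SE 0.11, adjusted p = 2.42e-05) in WTHK2, and Kdm2a, a demethylase of histone H3, with -0.46 (SE 0.060, adjusted p = 4.80e-06) in WTHK2 and -0.50 (SE 0.060, adjusted p = 2.57e-06) in LAC. Ubiquitin-specific proteases were lower in 17 of 34 cases and higher in 0 in WTHK2, and lower in 19 and higher in 1 in LAC (adjusted p = 3.91e-04 and 4.02e-04, and adjusted p = 0.138 and 0.140 with an estimated correlation). In the same libraries genes for long proteins were lower in 47 of 55 cases in WTHK2 and 50 of 55 in LAC (medians -0.30 and -0.31), a list that holds Usp34, Usp9x and Dync1h1, and the family changes were not separated from that trend. The medians of these 4 families kept their sign in both comparisons with EV under both other scalings, and between WTHK2 and LAC 0 demethylases passed the threshold.

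Chaperonin subunits were higher in 2 of 6 cases in WTHK2 and 4 of 6 in LAC, and spliceosomal Sm and LSm genes in 9 and 10 of 15, with 2 and 1 lower (adjusted p = 0.108 and 0.0294 for chaperonin subunits, and 0.366 and 0.242 with an estimated correlation; adjusted p = 0.0226 and 0.00319 for Sm and LSm genes, and 0.240 and 0.140 with an estimated correlation). Kinesins and dyneins were lower in 12 of 28 cases in both groups, with 2 and 1 higher, and zinc finger genes named Zfp or Znf in 23 and 15 of 84, with 7 and 12 higher (adjusted p = 0.0195 and 0.0405 for kinesins and dyneins, and 0.240 and 0.292 with an estimated correlation; adjusted p = 0.117 and 0.930 for zinc finger genes). Translation initiation factors went both ways, 10 higher and 11 lower of 39 in WTHK2 and 15 and 9 in LAC, as did cyclins and cyclin-dependent kinases, 3 and 7 of 25 in WTHK2 and 6 and 7 in LAC. With an estimated correlation none of the 10 families passed in any comparison.

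The runs of neighbouring genes that passed between the libraries labelled WTHK2 and LAC numbered 5 and held 269 genes, and were also sought only after the data were seen. From Noc2l to Dnajc11, 20 of 27 genes were higher in WTHK2 than in LAC (median log2 difference 0.24), with medians of 0.40 in WTHK2 and 0.12 in LAC against EV. From Xylt2 to Strada, 56 of 102 genes were higher (median 0.17), with medians of 0.17 and 0.013 against EV. From Dclre1a to Zfyve27, 30 of 55 genes were lower (median -0.17), with medians of -0.18 and -0.014, and from Rnf114 to Acss2, 44 of 70 were lower (median -0.19), with medians of -0.15 and -0.010. From Abcb10 to Itgb1, 7 of 15 genes were higher (median 0.17), with medians of 0.0036 in WTHK2 and -0.067 in LAC against EV. In the runs other than the last, the median had the same sign in all 3 libraries of WTHK2.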
